A study of Homo sapiens with 28 samples.

How the data were processed

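Gene expression was measured in Huh-7 cells, an established human hepatoma line, on Affymetrix arrays whose table lists 54675 probe sets. The 28 arrays fall into 7 groups of 4. One group received transfection reagent alone (Control). The other groups received LNA gapmers against glucocorticoid receptor RNA: gap-GR14 at 45 nM and at 40 nM, gap-GR18-1 at 60 nM, gap-GR18-2 at 45 nM and at 40 nM, and gap-GR18-3 at 12.5 nM. A gapmer is an antisense oligonucleotide whose middle part lets RNase H cleave the bound RNA. Cells were transfected with a Lipofectamine reagent and RNA was isolated after 24 h with a Qiagen column kit. The sequences and lengths of the oligonucleotides are not used here. Groups were taken from the sample titles, and no sample was left out. Whether the replicates come from independent cultures on different days is not stated, so every p-value measures only the spread between samples that may be technical replicates.

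The deposited values are signal intensity from MAS5 on a linear scale, named as such in the submitters' processing notes. The authors hybridized biotinylated cRNA made from 150 ng of total RNA. The mean of each array after trimming 2% of values was 500.1, so the arrays had been scaled by the authors to a common trimmed mean near that value, and no other normalization between arrays was found in the values. The version of the software, its background settings and its detection calls are not given in the sources used here. Scan dates and hybridization batches are not given either, so batches could not be examined. For arrays, precision is limited by the number of replicates and by signal over background. No column of sample values was left unused (0 columns).

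Values under the 20th percentile of all deposited values pooled, a signal of 12.4, were set to that value, and log2 was taken. Of all probe sets, 41091 list a single gene, 1801 list several genes, 11721 list no gene, and 62 are array controls. The filter was the 50th percentile of mean log2 signal over the 28 arrays. It was passed by 27306 probe sets, of which 4105 list no single gene and were not used for the genes tested. Each gene was represented by its probe set with the highest mean, with sets prone to hybridizing across genes used only where no other passed, which gave 12478 genes tested. Gene symbols were updated through the gene ID in a RefSeq gene table of assembly GRCh38.p14, which held the gene of 41037 single-gene probe sets. That table served for names and for the length of each gene's genomic span, and 12471 of the tested genes (99.9%) had a span.

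Each gene was fitted in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend) with 1 mean per group over all 28 arrays and no covariate. Contrasts were each condition against Control, gap-GR14 against gap-GR18-2 at each matched dose, the dose step within each of these compounds, the compound by dose interaction, and gap-GR18-1 and gap-GR18-3 against gap-GR14 at unmatched doses. Tests were two-sided moderated tests with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05, and a second count asked for a change of at least 2-fold. Single measures such as NR3C1 signal and array quality were compared by exact two-sided permutation tests of 4 arrays against 4.

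The gene lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names NR3C1 always. In each comparison it takes genes called with at least a 2-fold change whose 4 arrays in one group all lie beyond the 4 in the other. It names the 8 largest rises and 8 largest falls at 45 nM, 60 nM and 12.5 nM, and the 4 largest of each at 40 nM. For each gene list it names up to 4 called members with the largest change, or, where none was called, the 2 with the smallest adjusted p. Named genes with an uncertain probe set target are given for completeness only, and a few named by the rule are left out of the text for length.

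The lists covered glucocorticoid-induced, NF-kB and inflammatory, acute phase, interferon-stimulated, p53 target, integrated stress response, endoplasmic reticulum chaperone, heat shock, NRF2 target, cholesterol, fatty acid synthesis, fatty acid oxidation, hepatocyte secreted protein, hepatocyte transcription factor, S phase, G2 and mitosis, apoptosis, immediate early, TGF-beta and extracellular matrix, oxidative phosphorylation, cytosolic ribosomal protein, steroid receptor family, and RNase H and RNA decay genes, and markers of fibroblasts and stellate cells, endothelial cells, leukocytes and cholangiocytes. Of these, 26 were tested. Endothelial markers were not tested as a list because only 2 of the 10 passed the filter. Lists were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated for each list, and with fry, with adjustment over the lists within a comparison. Members were counted at the adjusted p over all genes and adjusted over the list alone.

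Overlaps between conditions were set beside the count expected for independent calls, beside 20 simulated data sets of unchanged groups compared with the same controls, and beside overlaps in which the controls were split between the conditions in 3 ways. Genes called under gap-GR14 at one dose against Control were compared between gap-GR14 and gap-GR18-2 in the arrays of the other dose, which took no part in the choice. Median spans of called genes were set beside those of genes not called. They were tested against random sets of equal size from all genes tested, with 1e+05 draws.

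The procedure was tested on simulated data with the layout of gap-GR14 at 45 nM against Control and 12478 genes. The simulated genes varied independently and at most 200 were changed, far fewer than the real contrast called. Correlation within lists and effects of scaling were therefore not covered. Of 50 genes changed at each size, 84% were recovered at 1.5-fold, 76% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 5 false calls. An unchanged condition gave 0 calls, and 160 of 200 genes were called in a simulated interaction. With 1 list raised, 2 of 26 lists were called. Both doses shared 193 of 200 genes set lower. The median span of called genes was 139.4 kb against 140.3 kb for the genes set lower, and a shift set to 1 on the log2 scale in held-out arrays was recovered as 1.00.

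Alternatives were quantile normalization, centring of each array on its median, no floor, the floor value as a pseudocount, no filter on low signal, a stricter filter on mean signal, the mean of all passing probe sets of a gene, only the groups compared in the fit, array weights, the replicate number as a block, an estimated correlation within lists, the other definition of a call, and leaving out each replicate in turn. A covariate for the ACTB 3'/5' ratio was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.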

Results

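Transcript levels were measured on arrays in Huh-7 cells 24 h after transfection with LNA gapmers designed against the RNA of the glucocorticoid receptor, which is encoded by NR3C1. The 28 arrays comprised 4 without oligonucleotide (Control) and 4 in each of 6 conditions: gap-GR14 at 45 nM and 40 nM, gap-GR18-1 at 60 nM, gap-GR18-2 at 45 nM and 40 nM, and gap-GR18-3 at 12.5 nM. The comparisons address how far each oligonucleotide lowers its target and how far other transcripts change with it. No group received an oligonucleotide directed at something else. A change against Control can therefore come from loss of NR3C1, from action on other transcripts or from the delivery of any oligonucleotide. Log2 signals of arrays from the same group correlated across probe sets at Pearson's r between 0.983 and 0.990, where probe sets are not independent replicates. The array's 75th percentile of signal was 415 ± 2.24 (SD, n = 4) in Control, on arrays scaled to a common trimmed mean. It was 320 ± 4.03 and 326 ± 2.30 under gap-GR14 at 45 and 40 nM, 360 ± 1.56 and 364 ± 1.63 under gap-GR18-2, and 402 ± 1.98 under gap-GR18-3 (exact two-sided permutation test, p = 0.0286, Benjamini-Hochberg p = 0.0343 for each of the 5), and 410 ± 2.59 under gap-GR18-1 (exact p = 0.0857). The ACTB 3'/5' signal ratio, a measure of RNA integrity, was 1.07 in Control, 1.12 under gap-GR14 at both doses, and 1.11 at 45 nM and 1.14 at 40 nM under gap-GR18-2 (exact p = 0.0286, Benjamini-Hochberg p = 0.0429 for each of the 4). It was also above Control under gap-GR18-1 (1.098) and gap-GR18-3 (1.094), each with exact permutation p = 0.0571 before and after correction. The GAPDH ratio gave adjusted exact p-values of 0.643 or more. Changes below are log2 differences ± SE from limma over 4 arrays per group, and where arrays lie at the floor the size of a change depends on the floor.

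NR3C1 fell under every oligonucleotide. On the probe set used its signal was 1173 ± 85.0 (SD, n = 4) in Control. It was 6.15% ± 0.887 of that level (SD, n = 4) under gap-GR14 at 45 nM and 6.76% ± 1.56 at 40 nM. It was 7.39% ± 1.37 under gap-GR18-1 at 60 nM, 5.88% ± 0.80 under gap-GR18-2 at 45 nM, 7.49% ± 1.08 at 40 nM, and 5.24% ± 0.487 under gap-GR18-3 at 12.5 nM. All 4 treated arrays lay below all 4 Control arrays in each condition (exact two-sided permutation test, p = 0.0286, the smallest this design allows), and all 5 NR3C1 probe sets fell in all 6 conditions. The residual share differed between probe sets: under gap-GR14 at 45 nM the others gave 3.36% (2 arrays at the floor), 6.94%, 15.9% and 21.2% (3 arrays at the floor). On the probe set used no difference in residual NR3C1 level was called among the 15 pairs of conditions after correction, with a lowest adjusted p of 0.0878 in limma. The largest were 0.51 for gap-GR18-2 at 40 nM minus gap-GR18-3 (uncorrected 95% interval 0.14 to 0.88) and 0.48 for gap-GR18-1 minus gap-GR18-3 (0.12 to 0.85). On another probe set, of the type prone to hybridizing across genes, the level was 4.29% ± 0.498 of Control (SD, n = 4) under gap-GR18-3. In the other conditions that set gave 6.48% to 7.03%, and pairs of conditions were not tested on it. At the matched dose of 45 nM gap-GR14 minus gap-GR18-2 was 0.06 on the probe set used (95% interval −0.31 to 0.43), an interval that leaves room for a modest difference in either direction. Treated means on the probe set used, from 61.4 to 87.8, lay near the array medians (group means from 61.6 to 66.9). Background could therefore narrow differences in residual level.

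**Figure D1:**
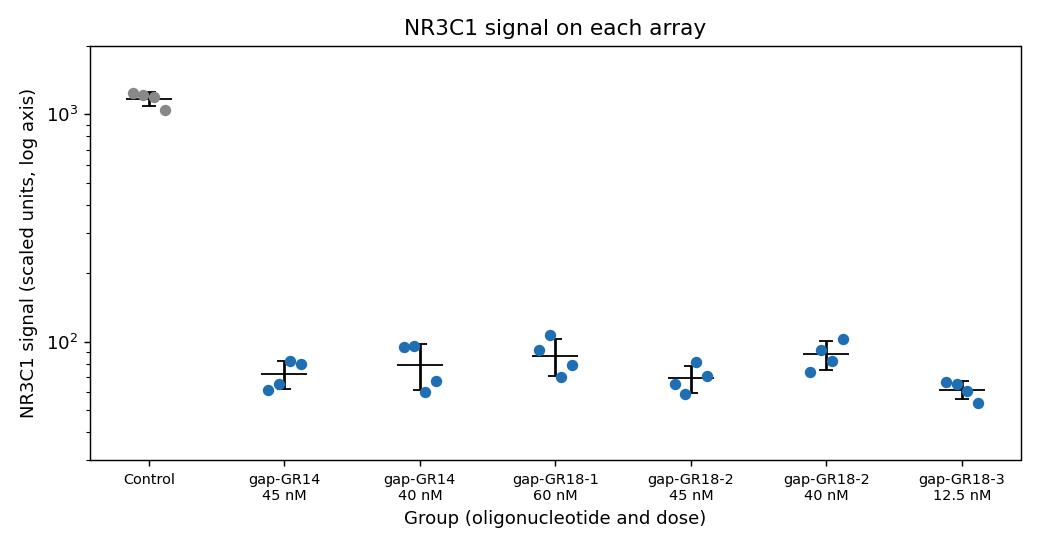
NR3C1 signal in scaled units (vertical axis, logarithmic) by group (horizontal axis), with each point an array and bars for the mean and SD of 4 arrays. The means of the 6 treated groups lie between 5.24% and 7.49% of the Control mean.

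Under gap-GR14 at 45 nM a large part of the transcriptome changed. The largest rises included FERMT3, an integrin activator of blood cells, at 586 ± 30.5 (SD, n = 4) against 13 ± 6.52 in Control, where 2 of the 4 arrays were at the floor. ZNF280A rose from 160.4 ± 19.6 to 3631 ± 253, CCK, the gut hormone cholecystokinin, rose from 67.4 ± 19.1 to 1088 ± 33.9, and SNAI2, a transcription factor of epithelial-mesenchymal transition, rose by 4.32 ± 0.28 (1 Control array at the floor). ADM5 and EPHB3 rose by 4.49 and 4.13 on the log2 scale, and CEL and CCL26, at the floor in 3 and 2 of the 4 Control arrays, by 4.59 and 4.36. SEL1L3 showed the largest fall, from 3873 ± 270.1 to 159 ± 26.7 (24.6-fold). Other SEL1L3 probe sets above the filter gave −3.92 and −2.73. CDYL, RPS6KC1, TRDMT1, CCDC88A, GLIS3, TRAF6 and TUBGCP3, the last a component of the gamma-tubulin complex, each fell, with changes from −4.36 to −4.60, where RPS6KC1 and TRDMT1 were at the floor in 1 and 2 of the treated arrays. Weaker falls came from other probe sets of TUBGCP3 (−3.13), GLIS3 (−2.70), TRAF6 (−1.82) and CCDC88A (−3.08, −2.61 and −0.78).

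In that comparison 4517 of the 12478 genes tested were called higher and 4645 lower in limma, of which 1177 rose and 2263 fell at least 2-fold. The share of the 2-fold changes that were rises depended on scaling: it was 34.2% as deposited and 46.2% after quantile normalization, with 1606 rises and 1871 falls. Quantile normalization also moved the median change of all genes from 0.02 to 0.12, and centring on array medians moved it to 0.13.

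Lists of stress and immediate early genes rose under gap-GR14 at 45 nM. Of 25 tested genes of the integrated stress response, 20 rose and 2 fell, among them DDIT4 by 2.91 ± 0.08, the glutathione-degrading enzyme CHAC1 by 1.69 ± 0.14, MTHFD2 by 1.66 ± 0.07 and the amino acid transporter subunit SLC3A2 by 1.55 ± 0.05 (camera adjusted p = 0.000276; adjusted p = 0.0892 with an estimated correlation). Of 20 immediate early genes, 18 rose and 1 fell, with FOSB up by 2.78 ± 0.21, KLF4 by 2.14 ± 0.06, EGR1 by 1.88 ± 0.09 and FOS by 1.72 ± 0.10 (adjusted p = 1.39e-05; adjusted p = 0.0892 with an estimated correlation). Of 13 heat shock genes, 11 rose and 2 fell, with BAG3 up by 1.42 and DNAJB1 by 1.38 (adjusted p = 0.00529; adjusted p = 0.0892 with an estimated correlation; no call after quantile normalization, which left 8 rising). Of 18 endoplasmic reticulum chaperones, 13 rose and 3 fell, with HERPUD1 up by 1.13 and CALR by 0.90 (adjusted p = 0.0143; adjusted p = 0.0892 with an estimated correlation, and no call after quantile normalization). Of 6 cholangiocyte markers, 5 rose, including CLDN4 by 2.47 ± 0.14, SOX9 by 1.29 ± 0.07 and KRT19 by 0.81 ± 0.04 (adjusted p = 0.0149; adjusted p = 0.0892 with an estimated correlation, and no call after quantile normalization).

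Oxidative phosphorylation and ribosomal protein genes gave calls in that comparison that ended with scaling, and camera's direction turned for the ribosomal list. Of 23 oxidative phosphorylation genes, 16 rose and 6 fell, and their median stood 0.29 above that of all genes as deposited and −0.08 after quantile normalization, where 9 rose and 7 fell (camera adjusted p = 0.029, then 0.992; adjusted p = 0.392 with an estimated correlation). NDUFB5 fell by 1.89 and COX7B rose by 0.73. Of 17 ribosomal protein genes, 15 rose, including RPS9 by 0.34 and RPL18 by 0.33, with a median 0.21 above that of all genes as deposited and −0.11 after quantile normalization, where 4 rose and 2 fell (adjusted p = 0.029, then 0.992; adjusted p = 0.534 with an estimated correlation).

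The remaining lists had called members under gap-GR14 at 45 nM without a list call. Glucocorticoid-induced genes went both ways, with 11 of 25 rising and 6 falling: RGS2 rose by 2.90 ± 0.04, the kinase SGK1 by 2.88 ± 0.05 and TSC22D3, which encodes the glucocorticoid-induced leucine zipper, by 1.85 ± 0.06, while LPIN1 fell by 2.77 (camera adjusted p = 0.102). Of 20 NF-kB and inflammatory genes 12 rose and 3 fell, with PTGS2, the inducible cyclooxygenase, up by 3.25 ± 0.18 (adjusted p = 0.0568). Of 22 p53 targets 15 rose and 4 fell, with the cell cycle inhibitor CDKN1A up by 1.87 ± 0.09 (adjusted p = 0.0555). Of 17 apoptosis regulators 12 rose and 3 fell, with PMAIP1 up by 3.50 and CASP8 down (fell by 2.18; adjusted p = 0.0909). Replication genes included both the polymerase subunit POLA1, which fell by 3.22 ± 0.19, and ORC1, which rose by 1.67, in a list of 25 with 13 rises and 7 falls as deposited and 11 and 10 after quantile normalization (adjusted p = 0.27). Of 27 G2 and mitosis genes 17 rose and 10 fell, including AURKA up by 1.66, while CENPF fell by 1.98 (adjusted p = 0.0555). The TGF-beta receptor TGFBR2 fell by 3.25 ± 0.06 and TIMP3 fell by 2.27 in a list of 17 with 6 rises and 9 falls, 7 and 7 on median-centred arrays (adjusted p = 0.602).

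Other lists in that comparison gave the following. Of 20 interferon-stimulated genes 10 rose and 5 fell, with IFIT1 up by 2.58 while RIGI fell by 1.62 (camera adjusted p = 0.393). Of 21 NRF2 targets 14 rose and 6 fell, with OSGIN1 up by 1.86 while ME1 fell by 2.86 and GCLM fell by 2.39 (adjusted p = 0.176); relative to all genes their median was positive as deposited and −0.01 after quantile normalization. Cholesterol genes (9 rose and 5 fell of 19; LSS fell by 1.27; adjusted p = 0.442), fatty acid synthesis genes (9 and 5 of 16; ACSS2 fell by 1.92; adjusted p = 0.393) and fatty acid oxidation genes (7 and 7 of 18; HADHB fell by 1.45; adjusted p = 0.991) were mixed. Of 24 hepatocyte secreted proteins 15 rose and 3 fell as deposited and 8 rose and 8 fell after quantile normalization (adjusted p = 0.124), and APOB fell by 0.88. Of 11 hepatocyte transcription factors 2 rose and 7 fell, and NR5A2 fell by 1.79 ± 0.10 (adjusted p = 0.393). Of 11 acute phase genes 1 rose and 2 fell as deposited, 2 rose and 1 fell on median-centred arrays, and HAMP, which encodes hepcidin, fell by 0.99 (adjusted p = 0.908). Of 6 genes of the steroid receptor family 2 rose and 4 fell, where the coactivators NCOA1 and NCOA2 fell (−3.42 and −2.22; adjusted p = 0.176). Of 17 RNase H and RNA decay factors 8 rose and 6 fell: the exosome subunits EXOSC3 and EXOSC10 fell (−3.82 and −2.25), and UPF1 rose by 1.37 (adjusted p = 0.944). Fibroblast and stellate markers (3 of 9 rose; PDGFRA by 3.07; adjusted p = 0.344) and leukocyte markers (3 of 6 rose; CD14 by 2.06; adjusted p = 0.288) had no falls called, and of the endothelial markers LYVE1 rose by 0.58 and PECAM1 fell by 0.37, although the mean of the PECAM1 probe sets gave a called rise of 0.87. Counts adjusted over the list alone equalled those over all genes for each of the 26 lists. The mean and the median of a list had opposite signs for fatty acid synthesis, fatty acid oxidation, S phase and RNA decay genes, whose camera direction followed the median.

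At 40 nM gap-GR14 gave a similar picture. FERMT3, CEL, ZNF280A and ADM5 rose by 4.88 ± 0.45, 4.43 ± 0.36, 4.30 ± 0.09 and 4.14 ± 0.57, with FERMT3 and CEL at the floor in 2 and 3 Control arrays. AFAP1L1 (1 array at the floor), the centrosomal gene CEP63, TUBGCP3 and EVI5 fell (−4.92 ± 0.27, −4.70 ± 0.29, −4.60 ± 0.18 and −4.52 ± 0.16). Other probe sets gave −0.88 for AFAP1L1, −3.14 for CEP63 and −3.11 for TUBGCP3. Against Control 4504 genes rose and 4537 fell, with 1064 and 2137 of them changed at least 2-fold, 33.2% of these being rises, or 45.5% after quantile normalization (1465 and 1757). That normalization moved the median of all genes from 0.02 to 0.12, and median centring moved it to 0.14. Camera called 7 lists here too, none of them with an estimated correlation (adjusted p from 0.0983 to 0.484). Of the 7, the integrated stress response (adjusted p = 0.00042) and immediate early genes (adjusted p = 2.64e-05) were also called under quantile normalization. The calls of heat shock genes, endoplasmic reticulum chaperones, cholangiocyte markers, oxidative phosphorylation and ribosomal proteins ended under it, the ribosomal list going from 15 rises and 0 falls (16 and 0 adjusted over the list alone) to 5 and 2, with medians relative to all genes of 0.22 and −0.10, and oxidative phosphorylation from 0.27 to −0.10.

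Under gap-GR18-1 at 60 nM far fewer genes changed strongly, and falls dominated. ANK3, which encodes the membrane scaffold ankyrin-G, fell from 1509 ± 21.9 (SD, n = 4) to 98.2 ± 20.9, and by 2.23 on the log2 scale on another probe set. DENND5B, PLA2G4A, the ion channel TRPM7, RAB27B, the circadian repressor CRY1 and RMND5A fell (−3.71 ± 0.19, −3.47 ± 0.16, −3.40 ± 0.22, −3.33 ± 0.17, −3.31 ± 0.07 and −3.13 ± 0.11). Other DENND5B probe sets above the filter gave −3.65 and −2.56. Among the rises were CEL by 2.54 ± 0.36 (3 Control arrays at the floor), ADM5 by 2.52 ± 0.57, the chemokine receptor CCR7 by 2.41 ± 0.33, MOGAT1 by 2.30 ± 0.29 and DCHS1 by 2.07 ± 0.22. The rule also named NBPF20, GSTT2 and SPRY4-IT1 among the rises, which belong to multicopy families or lie within another gene, so that their probe sets are uncertain. In total 3143 genes rose and 2315 fell, of which 150 and 334 changed at least 2-fold.

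Of 25 integrated stress response genes 15 rose and 2 fell under gap-GR18-1 (17 and 2 adjusted over the list alone), led by DDIT3 at 1.15 ± 0.08 and STC2 at 1.11 ± 0.07 (camera adjusted p = 0.0031; adjusted p = 0.123 with an estimated correlation). Of 19 cholesterol genes 12 rose and 2 fell, with TMEM97 up by 0.50 and HSD17B7 by 0.49 (adjusted p = 0.0274, and 0.0616 with an estimated correlation). Of 25 S phase genes 15 rose and 3 fell, with CDT1 up by 0.65 and CCNE2 by 0.58, although CDC45 fell by 1.88 and POLA1 fell by 1.30 (adjusted p = 0.0428, and 0.123 with an estimated correlation). Of 17 TGF-beta and matrix genes 8 fell, including TGFBR2, which fell by 1.15, TGFB2, which fell by 0.81, and TIMP3, which fell by 0.73 (adjusted p = 0.0291, and 0.0616 with an estimated correlation). Glucocorticoid-induced genes had 7 rises and 7 falls among 25, with ANGPTL4 up by 1.04, while CEBPD fell by 1.27 and LPIN1 fell by 1.02 (adjusted p = 0.773).

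Under gap-GR18-2 at 45 nM the changes were intermediate in number. The transcription elongation factor TCEA2 rose from 43.1 ± 42.0 (SD, n = 4) to 472 ± 91.6, with 1 Control array at the floor, and ZNF280A from 160.4 ± 19.6 to 1529 ± 88.3, and ZCCHC12, ZPLD1 and ZNF335 rose by 3.20 ± 0.13, 2.72 ± 0.12 and 2.66 ± 0.34, where other ZPLD1 and ZNF335 probe sets gave 0.97 and 0.55. The metalloproteinase MMP10 rose by 3.25 ± 0.31, with 2 Control arrays at the floor. NR4A1, an orphan nuclear receptor, rose by 2.86 ± 0.25 on the probe set used and 1.45 on another that passes the filter, but without the filter another probe set represents NR4A1 and gives −0.062. NBPF20, of a multicopy family, gave 4.38 ± 0.16. Besides NR3C1, GLIS3 fell 33.5-fold to 24.0 ± 18.0, with 1 array at the floor, although another GLIS3 probe set gave −2.61, and ZNRF3, a ubiquitin ligase that limits Wnt signalling, fell by 4.23 ± 0.24. The RNA-binding protein gene MSI2 fell 16.5-fold, with changes from −1.86 to −4.07 on 6 other probe sets above the filter, and the adhesion molecule NRCAM, LRRC34 (2 arrays at the floor) and SHANK2 fell (−3.96 ± 0.11, −3.91 ± 0.27 and −3.80 ± 0.12). Another NRCAM probe set gave −2.26.

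In total 4508 genes rose and 4113 fell under gap-GR18-2 at 45 nM, of which 765 and 1534 changed at least 2-fold. Rises made up 33.3% of these as deposited, 44.2% after quantile normalization (1040 and 1312) and 43.7% on median-centred arrays (1021 and 1316), where the median of all genes moved from 0.03 to 0.13. Of 25 integrated stress response genes 21 rose and 3 fell, with DDIT3 up by 1.72 ± 0.08, SLC3A2 by 1.45 ± 0.05 and CTH by 1.30 ± 0.07 (camera adjusted p = 0.000152; adjusted p = 0.0769 with an estimated correlation). Of 22 p53 targets 13 rose and 1 fell, including TP53I3 by 0.96 ± 0.04 and CCNG1 by 0.90 ± 0.03 (adjusted p = 0.0183, and 0.0769 with an estimated correlation). Of 20 immediate early genes 16 rose and 4 fell, with FOSB up by 1.33 ± 0.21 (adjusted p = 0.0183, and 0.389 with an estimated correlation). Of 17 TGF-beta and matrix genes 3 rose and 11 fell, where TIMP3 fell by 1.48 ± 0.08 and the laminin chain LAMB1 fell by 1.36 ± 0.06 (adjusted p = 0.0293, and 0.0769 with an estimated correlation). Of 25 glucocorticoid-induced genes 12 rose, such as TSC22D3 (2.82-fold), and 9 fell, where CRISPLD2 fell by 1.85 ± 0.13 (adjusted p = 0.582).

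At 40 nM gap-GR18-2 raised TCEA2 by 3.78 ± 0.43 (1 Control array at the floor), ZNF280A by 3.23 ± 0.09 and ZCCHC12 by 2.95 ± 0.13. PTPN14, a phosphatase, fell by 4.16 ± 0.36, ZNRF3 fell by 4.08 ± 0.24, and the ceramide synthase CERS4 fell by 3.97 ± 0.44, with 2 arrays at the floor. In total 4403 genes rose and 4065 fell, of which 687 and 1402 changed at least 2-fold, 32.9% of these being rises, or 42.9% after quantile normalization (926 and 1230). The same 4 lists passed camera: the integrated stress response (21 rose and 3 fell; adjusted p = 0.000128), p53 targets (12 and 1, or 12 and 0 adjusted over the list alone; adjusted p = 0.0158), immediate early genes (14 and 4; adjusted p = 0.0305, with no call after quantile normalization) and TGF-beta and matrix genes (3 and 13; adjusted p = 0.0158). With an estimated correlation their adjusted p were 0.073, 0.054, 0.414 and 0.054.

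Under gap-GR18-3 at 12.5 nM a short set of transcripts fell strongly on the probe sets used. ZNRF3 fell to 60.6 ± 21 (SD, n = 4) from 1119 ± 100.2 in Control, TUBGCP3 fell 18.3-fold, and CCDC92 (1 array at the floor), the proton pump subunit ATP6V1H, RAB27B, the ubiquitin ligase scaffold CUL4A and BRAP fell (−4.22 ± 0.30, −4.05 ± 0.16, −4.00 ± 0.17, −3.93 ± 0.15 and −3.92 ± 0.16). Other probe sets gave −0.56 for ATP6V1H and −2.81 for TUBGCP3. The glycosyltransferase B3GNT7, CEL and CALHM6 rose by 2.93 ± 0.39, 2.84 ± 0.36 and 2.41 ± 0.32, with 1, 3 and 1 Control arrays at the floor, but other B3GNT7 probe sets above the filter gave −0.10 and 1.22. LIAT1 (1 Control array at the floor), CYB561, EMP1 and PIERCE1 rose by 2.30, 2.21, 2.16 and 2.03. Another PIERCE1 probe set gave 4.07. In total 3586 genes rose and 2204 fell, of which 188 and 479 changed at least 2-fold. Of 25 integrated stress response genes 22 rose and 2 fell, with STC2 up by 1.42 ± 0.07, DDIT4 by 0.86 ± 0.08 and TRIB3 by 0.74 ± 0.06 (camera adjusted p = 5.71e-05; adjusted p = 0.172 with an estimated correlation). It was the 1 list of 26 that passed camera. Glucocorticoid-induced genes had 9 rises and 7 falls among 25 (10 and 7 adjusted over the list alone), with TSC22D3 up by 1.32 ± 0.06 and IGFBP1 by 0.88 ± 0.14 (adjusted p = 0.779). Among single members of other lists the complement gene C3 fell by 0.98 ± 0.09, the acetyl-CoA synthetase gene ACSS2 fell by 2.31 ± 0.12, TYMS fell by 1.00 ± 0.04 and TGFBR2 fell by 2.04 ± 0.06. Others rose, such as OSGIN1 by 1.095 ± 0.095 and PTGS2 by 1.07 ± 0.18.

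**Figure D2:**
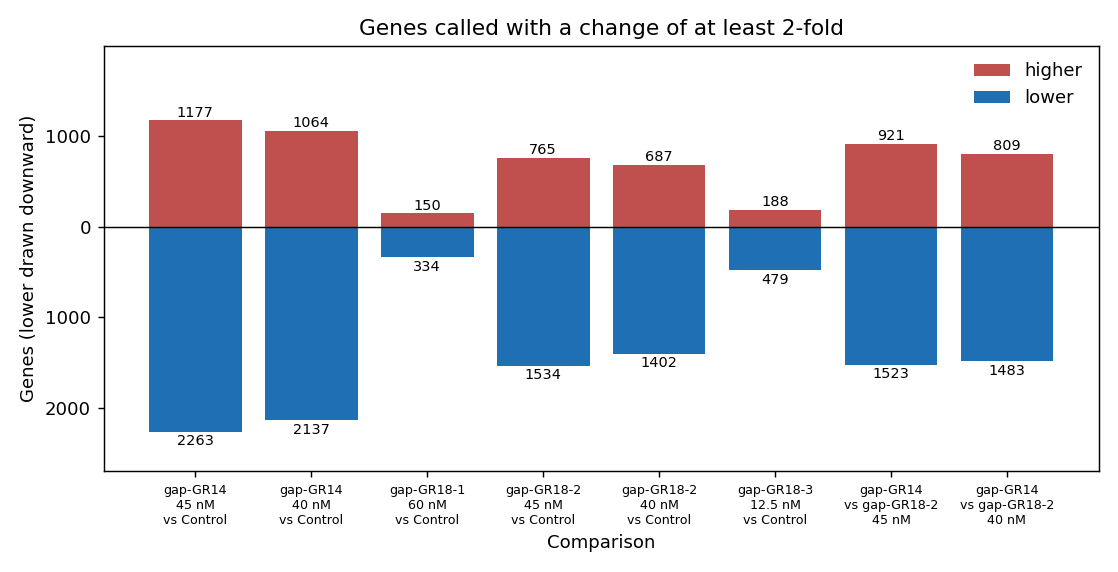
Number of genes (vertical axis) called higher (upward bars) or lower (downward bars) by at least 2-fold in each comparison with Control and between gap-GR14 and gap-GR18-2 (horizontal axis), of 12478 genes tested in limma with 4 arrays per group. Counts against Control run from 150 and 334 under gap-GR18-1 to 1177 and 2263 under gap-GR14 at 45 nM.

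Gap-GR14 and gap-GR18-2 could be compared at matched doses. At 45 nM signal was lower under gap-GR14 than under gap-GR18-2 for ZNF165 (14.5 ± 10.8, with 2 arrays at the floor, against 1267 ± 49.8; SD, n = 4; 281 ± 39.6 in Control), ALDH9A1 (156 ± 27.5 against 3247 ± 203) and TRAF6, a ubiquitin ligase of inflammatory signalling (25.1 ± 16.7 against 667 ± 98.2). CDADC1 and the protocadherin PCDH17 were lower by −4.21 ± 0.10 and −3.78 ± 0.15. Other probe sets gave −2.74 for TRAF6 and −3.72, −2.85 and −1.60 for CDADC1. Part of these gaps is a rise under gap-GR18-2, by 2.18 ± 0.20 for ZNF165 and 1.81 ± 0.10 for CDADC1 against Control. The antisense transcript SBF2-AS1 was at least 19.7-fold lower, with all 4 gap-GR14 arrays at the floor, and NBPF20 was lower by −3.89 ± 0.16, although it was above Control under both (285 ± 108 and 4007 ± 287 against 193 ± 25.7). TTLL4 was lower by −3.90 ± 0.34 on the probe set used, whereas other TTLL4 probe sets gave 0.07 and −1.84. Higher under gap-GR14 were MSL3 by 4.07 ± 0.09, LPCAT1 by 3.98 ± 0.37, CEP97 by 3.63 ± 0.31 (3 gap-GR18-2 arrays at the floor), MAST3 by 3.50 ± 0.43 (1 at the floor), MTCL1 by 3.49 ± 0.11, FBRSL1 by 3.14 ± 0.09, NECAB2 by 3.11 ± 0.46 (1 at the floor) and the metal transporter SLC39A14, at 11526 ± 338 against 1311 ± 31.2. Other probe sets above the filter gave 0.65 for MSL3, and 2.53 and 0.55 for FBRSL1. Each of these higher genes had a mean below Control under gap-GR18-2, so part of each gap is a lower level there. LPCAT1 was at 640 ± 46.0 (SD, n = 4) in Control, 879 ± 95.9 under gap-GR14 and 66.5 ± 34.8 under gap-GR18-2. MTCL1 was at 944 ± 27.8, 1463 ± 147 and 130 ± 10.6. SLC39A14 was at 15851 ± 112 in Control and so was below Control under both compounds.

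At 45 nM 4089 genes were higher and 4360 lower under gap-GR14 than under gap-GR18-2 in limma, 921 and 1523 of them by at least 2-fold. Which direction had more calls depended on scaling: after quantile normalization 4449 were higher and 4101 lower, while by at least 2-fold lower genes stayed more numerous (1056 and 1301, or 44.8% higher against 37.7% as deposited). Immediate early genes were higher, 16 of 20 with none lower, including FOSB by 1.46 ± 0.21 and KLF4 by 1.35 ± 0.06 (camera adjusted p = 0.000383; adjusted p = 0.23 with an estimated correlation). Glucocorticoid-induced genes were higher for 19 of 25 and lower for 4, with SGK1 at 1.59 ± 0.05, RGS2 at 1.58 ± 0.04 and LPIN1 at −2.66 ± 0.08 (adjusted p = 0.014, and 0.23 with an estimated correlation). Heat shock genes were higher for 10 of 13 and lower for 1, with BAG3 at 1.27 ± 0.04 (adjusted p = 0.0199, and 0.23 with an estimated correlation, with no call after quantile normalization). Mitotic genes went to extremes in both directions, with CENPF at −3.06 ± 0.07, BIRC5 at 2.55 ± 0.04 and DLGAP5 at 2.51 ± 0.06 (13 higher and 8 lower of 27; adjusted p = 0.227). CASP8, the initiator caspase of death receptors, was lower by −3.03 ± 0.11.

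At 40 nM ZNF165, ALDH9A1, SBF2-AS1 and CDADC1 were lower under gap-GR14 by −5.34 ± 0.20, −4.59 ± 0.10, −4.19 ± 0.21 and −4.18 ± 0.10, with SBF2-AS1 at the floor in 3 gap-GR14 arrays, and MSL3, LPCAT1, MTCL1 and ADM5 higher by 3.94 ± 0.09, 3.51 ± 0.37, 3.43 ± 0.11 and 3.43 ± 0.57. Other probe sets gave −3.94, −2.83 and −0.72 for CDADC1 and 0.40 for MSL3. Under gap-GR18-2, LPCAT1 (87.9 ± 48.2; SD, n = 4) and MTCL1 (137 ± 36.3) were below Control (640 ± 46.0 and 944 ± 27.8). MSL3 was too (85.1 ± 4.34 against 371 ± 20.7 in Control), while ADM5 was not (55.9 ± 46.6 against 27.1 ± 13.5). There 4041 genes were higher and 4286 lower, 809 and 1483 by at least 2-fold, and 4392 higher and 4004 lower after quantile normalization, 971 and 1266 by at least 2-fold. Immediate early genes (15 higher and none lower of 20; adjusted p = 0.000467) and glucocorticoid-induced genes (16 higher and 4 lower of 25; adjusted p = 0.015) again passed camera, as did heat shock genes (11 and 1 of 13; adjusted p = 0.0136) and cholangiocyte markers (4 and none of 6; adjusted p = 0.0354), 2 lists whose calls ended after quantile normalization. Each of the 4 had an adjusted p of 0.198 with an estimated correlation.

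The step from 40 nM to 45 nM gave few called genes. Under gap-GR14, 4 genes rose and 27 fell, among them RAB22A (fell by 0.41), LANCL2 (fell by 0.41), the glutathione reductase gene GSR (fell by 0.22) and ZNF165 (fell by 0.90), while NPDC1 rose by 2.19 and FBXO36 by 1.46, and 1294 genes had an unadjusted p under 0.05 in limma. Under gap-GR18-2, 0 genes rose and 7 fell: HNMT, EEF2K, GLIS3, FNDC3B, GPR157, TBC1D1 and SLC39A14, of which GLIS3 fell by 1.64, and 1169 genes had an unadjusted p under 0.05. The dose step differed between the compounds for 1 gene, DPH3 (−0.26 ± 0.04, adjusted p = 0.0268), and 1074 genes had an unadjusted p under 0.05. The genes of these small counts were named after their values were seen. These counts moved by over 1.5 times with other settings: fitting only the groups compared gave 0 for each of the 3 contrasts, and leaving out 1 array gave 7 to 68 for gap-GR14, 3 to 52 for gap-GR18-2 and 0 to 13 for the interaction.

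Gap-GR18-1 and gap-GR18-3 were given at doses without a match, so the differences below mix compound and dose. Under gap-GR18-1 at 60 nM 1988 genes were higher and 737 lower by at least 2-fold than under gap-GR14 at 45 nM, and 1855 and 622 than at 40 nM. Under gap-GR18-3 at 12.5 nM 1998 were higher and 731 lower than under gap-GR14 at 45 nM, and 1877 and 650 than at 40 nM. The numbers of genes called in limma were 8919, 8729, 8736 and 8675. NR3C1 under gap-GR14 at 45 nM minus gap-GR18-3 was 0.22 (95% interval −0.14 to 0.59).

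Some genes were called in all 6 conditions, which share the same 4 Control arrays, and no count expected without change was computed for the 6 together. Because Control received no oligonucleotide, loss of NR3C1 and an effect of any oligonucleotide cannot be told apart for these genes. By at least 2-fold, 114 genes fell in all 6, including NR3C1, ZNRF3 (mean over conditions −3.94), RAB27B (−3.52), GLIS3 (−3.34), ATXN1 (−3.30), DTNA (−3.24) and the BMP receptor BMPR2 (−3.17). There were 30 that rose in all 6, among them ZCCHC12 (mean 2.78) and, with 2, 3 and 2 Control arrays at the floor, FERMT3 (3.14), CEL (3.12) and CCL26 (2.89). The means were ranked after the values were seen. TSC22D3 rose in each condition, by 0.65 under gap-GR18-1 and up to 1.85 under gap-GR14 at 45 nM. In 1 or more conditions 1679 genes rose and 3055 fell by that measure, and 58 rose in one condition and fell in another.

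Genes that fell under gap-GR18-1 mostly fell under gap-GR14 too: 299 of 334 were at least 2-fold lower under both at 60 nM and 45 nM, where independent calls would share 60.6. For gap-GR18-3 the shared falls with gap-GR14 at 45 nM numbered 363 of 479 (86.9 if independent) and for gap-GR18-2 at 45 nM 959 of 1534 (278 if independent). Both doses of gap-GR14 shared 2040 falls and 1014 rises. Gap-GR18-1 and gap-GR18-3 shared 125 falls (12.8 if independent). Because the conditions share Control arrays, overlaps with the controls split between conditions were also taken, and gave 292, 347.8, 932.7 and 119.8 shared falls for the pairs with gap-GR18-1, gap-GR18-3, gap-GR18-2 and for the last pair. The covariance of changes across genes was 0.289 for gap-GR14 and gap-GR18-1, against 0.0166 simulated for unchanged groups with the same controls. Covariance grows with the size of the changes. For that pair r was 0.586 against 0.485 simulated, and 66.8% of all genes changed in the same direction against 66.5% simulated. For gap-GR18-1 and gap-GR18-3 the covariance was 0.111 against 0.0171 simulated, but r was 0.483 against 0.494.

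Genes chosen at one dose of gap-GR14 against Control were then compared between gap-GR14 and gap-GR18-2 in the arrays of the other dose, which took no part in the choice. The 2137 genes that fell at least 2-fold at 40 nM, which include TUBGCP3, EVI5 and CEP63, had at 45 nM a median change of −1.74 under gap-GR14 and −0.85 under gap-GR18-2, measured from the Control arrays that also served for the choice. The median difference between these compounds was 0.97 (0.91 to 1.03 over the pairs of arrays; exact two-sided permutation test, p = 0.0286). Because the genes were chosen for a change under gap-GR14, the direction of this difference follows in part from the choice, and genes chosen under gap-GR18-2 were not examined. In the same genes the median change was −0.33 under gap-GR18-1 and −0.25 under gap-GR18-3. The 1064 genes that rose, which include FERMT3 and ZNF280A, had medians of 1.38 under gap-GR14 and 0.84 under gap-GR18-2, a difference of −0.66 (−0.69 to −0.65). With the doses exchanged the differences were 0.94 (0.85 to 1.01) and −0.60. Choosing all called genes in place of those changed at least 2-fold gave a smaller difference of 0.57 for the genes that fell and −0.30 for those that rose.

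Genes that fell were long. Under gap-GR14 at 45 nM the median genomic span was 99.6 kb for genes that fell at least 2-fold, 22.7 kb for genes not called and 14.7 kb for genes that rose. Against random sets of all genes tested (median 28.3 kb), fallen and risen genes each had a permutation p = 1e-05, the smallest that the draws can give. The medians of fallen genes were 157 kb under gap-GR18-1, 113 kb under gap-GR18-2 at 45 nM, 116 kb at 40 nM and 142 kb under gap-GR18-3, against 25.9, 24.1, 23.7 and 25.5 kb for genes not called. In the longest quintile of genes 50.3% fell under gap-GR14 at 45 nM, 36.5% under gap-GR18-2 at 45 nM and 13.1% under gap-GR18-3, and in the shortest quintile 3.81%, 1.88% and 0.441%. Genes at least 2-fold lower under gap-GR14 than under gap-GR18-2 at 45 nM had a median of 57.7 kb, and those higher 34.2 kb, against 22.6 kb for genes not called. Genes are not independent replicates, and with all called genes in place of those changed at least 2-fold the ratio of fallen genes to those not called was 2.78 in place of 4.38 under gap-GR14 at 45 nM.

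**Figure D3:**
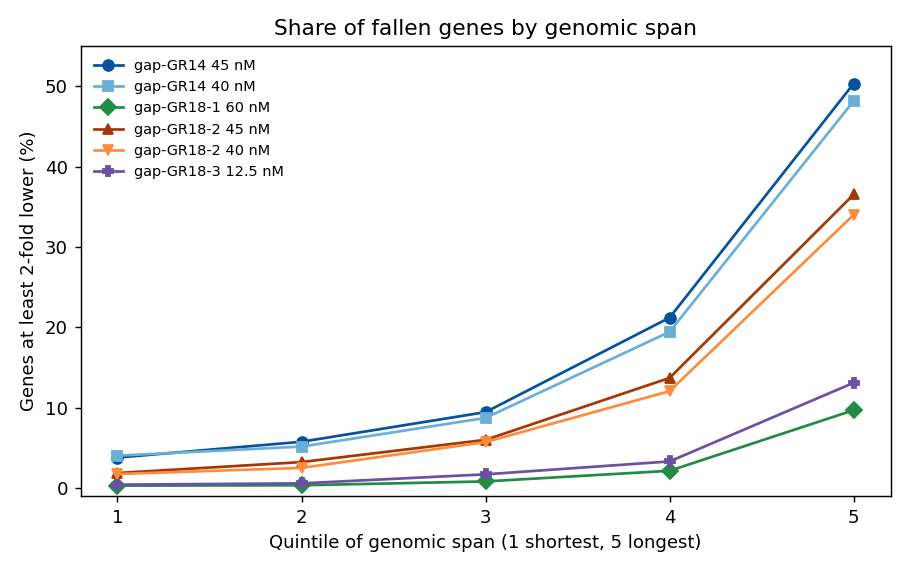
Percent of genes at least 2-fold lower than in Control (vertical axis) in each quintile of genomic span (horizontal axis, shortest to longest), with a line per condition over 12471 genes. Under gap-GR14 at 45 nM the percent goes from 3.81% in the shortest quintile to 50.3% in the longest.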

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

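The covariate for the ACTB ratio, the test of NR3C1 as the reason for the larger number of changes under gap-GR14, and the use of all 28 arrays in each refit of other splits (after a fit of 8 arrays had been seen) were chosen only after the result was seen.

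More genes changed at least 2-fold under gap-GR14 at 45 nM (3440) than under gap-GR18-1 at 60 nM (484) or gap-GR18-3 at 12.5 nM (667), ratios of 7.11 and 5.16. Against the authors' scaling as the whole cause, the lower of these ratios was 5.16 after quantile normalization. With the ACTB 3'/5' ratio as a covariate for RNA quality, the lower ratio was 5.11. That fit keeps 1 mean per group, so the covariate reads only differences between arrays of the same group. The ACTB ratio itself differed between groups (1.07 in Control, 1.12 under gap-GR14 at 45 nM). The covariate therefore cannot decide whether RNA quality plays a part. Against a stronger lowering of NR3C1 under gap-GR14 than under gap-GR18-3, the 95% interval of the difference in NR3C1, on the probe set used, reached down only to −0.14 on the log2 scale. Mean NR3C1 signal was 72.1 under gap-GR14 at 45 nM and 61.4 under gap-GR18-3, near their array medians of 62.3 and 66.3. Without detection calls, background in these signals could narrow that difference. Against gap-GR18-1 the interval ran from −0.63 to 0.11 (difference −0.26), so a stronger lowering stays open for that pair. Dose stays open for gap-GR18-3, given at the lower dose, while gap-GR18-1 was given at a higher dose than gap-GR14 and changed fewer genes, and a difference in how many other transcripts each compound lowers may be a biological explanation that only the matched comparison with gap-GR18-2 addresses.

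Genes that fell at least 2-fold under gap-GR14 at 45 nM had longer genomic spans than genes not called. Against a difference in signal level of long genes as the whole cause, the ratio of median spans within deciles of Control signal had a median of 3.82, or 4.02 without the lowest decile, which held 13 fallen genes and gave 0.978. A fall of long genes common to all the oligonucleotides was examined in the 618 genes not called lower under gap-GR18-2 at 45 nM. Their ratio was 2.18 (median span 49.6 kb, 45.2 to 52.7 kb over resampled genes), against 4.38 for all the fallen genes. The set can hold genes that fell under gap-GR18-2 without a call, and genes that fell under the remaining compounds. It therefore cannot decide whether a common fall is the whole cause. What stays open is that long precursor RNA may offer more places for an oligonucleotide to bind, which could not be examined without the sequences. A response of long genes to a shared effect of transfected oligonucleotide, alone or in addition, also stays open.

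TSC22D3, a gene that glucocorticoids induce, rose under gap-GR14 at 45 nM while NR3C1 fell. Whether cells were exposed to a glucocorticoid is not stated here, so how far TSC22D3 depended on NR3C1 in Control is not known. Against a probe set that reads another transcript, the other TSC22D3 probe set that passed the filter gave a change of 2.45, but it is of the type prone to hybridizing across genes, which the prediction did not allow for, and a further set under the filter was not called (0.96, adjusted p = 0.257), so this reading stays open in part. Against the authors' scaling, the change was 1.79 after quantile normalization. Induction of TSC22D3 by a route other than the receptor may stay as a hypothesis, and the data hold no further test of it. The list of glucocorticoid-induced genes as a whole went both ways.

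Other splits of the same 8 arrays gave fewer calls than the real split in 12 contrasts. There 1 of 35 splits (the real one) reached the real count, the smallest share possible, without correction over the contrasts. A split that mixes both groups adds their difference to the spread within groups, so fewer calls follow in part from the method. The splits also cannot tell treatment from a difference in culture, day or batch. The real count and the highest other were 9162 and 2850 for gap-GR14 at 45 nM, 9041 and 3651 at 40 nM, 5458 and 23 for gap-GR18-1, 8621 and 3565 for gap-GR18-2 at 45 nM, 8468 and 2686 at 40 nM, and 5790 and 134 for gap-GR18-3. They were 8449 and 4 for gap-GR14 against gap-GR18-2 at 45 nM and 8327 and 2 at 40 nM. Against gap-GR14 at 45 nM and 40 nM they were 8919 and 1, and 8729 and 1, for gap-GR18-1, and 8736 and 1, and 8675 and 2, for gap-GR18-3. For the dose step of gap-GR14 1 of 35 splits also reached the real count of 31, but the highest other gave 19, 31 of the other splits called some gene, and the count was 0 with only the groups compared in the fit and 1 on median-centred arrays, so the step is not held to be established. For the dose step of gap-GR18-2 chance was not excluded: 4 of 35 splits reached the real count of 7 and the highest other gave 112, several times as many, which points to a structure among those 8 arrays. In principal components 1 and 2, 40 nM replicate 3 lay at 6.96 and −45.06, nearer the 45 nM arrays (5.98 to 8.43 and −47.00 to −43.92) than the other 40 nM arrays (10.74 to 11.05 and −41.12 to −40.41). Without it the dose step called 18 genes, and without 45 nM replicate 1 it called 52; a mix-up of arrays was not tested. For the interaction chance was not excluded either, with 33 of 100 splits reaching the real count of 1 and a highest other of 15.

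DPH3 was singled out by a test of the difference itself: its dose step differed between gap-GR14 and gap-GR18-2 by −0.26 (limma, two-sided, adjusted p = 0.0268). The call is not held to be established. The interaction called 0 genes after quantile normalization, on median-centred arrays, with the mean of the probe sets and with only the groups compared in the fit.

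In 17 of 224 groups of 4 values a single array lay far from the other 3, where chance gives about 1 in 20. The number given is the gap to the nearest array divided by the range of the group. For the GAPDH 3'/5' ratio Control replicate 2 was at 0.953 against 0.982 to 0.987 (0.851). For the 20th percentile of signal gap-GR18-1 replicate 3 was at 14.1 against 12.1 to 12.4 (0.859), and for the median signal at 70.9 against 63.7 to 64.7 (0.858). The other 14 concern the mean log2 signal of a list: RNA decay factors in Control replicate 1 (0.861); acute phase genes (0.952) and oxidative phosphorylation (0.945) in gap-GR14 45 nM replicate 4; integrated stress response (0.833) and cholesterol genes (0.873, at 11.33 against 11.47 to 11.49) in gap-GR14 45 nM replicate 3. In gap-GR14 40 nM replicate 2 they were fatty acid synthesis (0.849) and S phase genes (0.850). In gap-GR18-1 they were fatty acid oxidation in replicate 3 (0.896) and TGF-beta genes in replicate 1 (0.835). In gap-GR18-2 they were NF-kB (0.929) and immediate early genes (0.862) in 45 nM replicate 1, immediate early genes in 40 nM replicate 3 (0.854) and endoplasmic reticulum chaperones in 40 nM replicate 4 (0.933). In gap-GR18-3 replicate 3 it was NRF2 targets (0.901).

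Of 4105 probe sets that pass the signal filter and list no single gene, which no comparison above uses, 927 changed at least 2-fold under gap-GR14 at 45 nM (410 rose and 517 fell), 834 at 40 nM, 138 under gap-GR18-1 (70 rose and 68 fell), 561 under gap-GR18-2 at 45 nM, 513 at 40 nM and 147 under gap-GR18-3.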

How the results depend on the processing

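Of the alternatives in this part, the ACTB covariate was chosen only after the result was seen. NR3C1 kept its direction and its call in all 6 conditions under quantile normalization, median centring, no floor and the replicate block. It also did so on its other probe sets and without each replicate. The remaining alternatives were not examined for NR3C1. The 16 span results under other filters and calls kept their direction and their side of the threshold. Counts of genes called were within 1.5 times the reported count for the 6 conditions and the matched comparisons under each alternative that tests them. With the ACTB covariate the counts of genes changed at least 2-fold were 3538, 3328, 483, 2384, 2247 and 693 for the conditions in the order of the report.

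Leaving out each replicate in turn gave 8959 to 9026 genes for gap-GR14 at 45 nM, 8806 to 8877 at 40 nM, 5050 to 5162 for gap-GR18-1, 8375 to 8508 and 8183 to 8297 for gap-GR18-2 at 45 and 40 nM, 5341 to 5537 for gap-GR18-3, and 8210 to 8319 and 8054 to 8158 for gap-GR14 against gap-GR18-2. The small counts moved more: 7 to 68 for the gap-GR14 dose step, 3 to 52 for the gap-GR18-2 dose step and 0 to 13 for the interaction; the cause was not tested. The extremes came without gap-GR14 45 nM replicates 4 and 1 for the first, gap-GR18-2 40 nM replicate 4 and 45 nM replicate 1 for the second. Of results for named genes 140 lost their call without a replicate (43 gene and comparison pairs) and 6812 did not.

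Under the other alternatives 115 results for named genes lost their call, 21 reversed and 8327 did neither. Quantile normalization reversed A2M under gap-GR18-2 at 45 nM (−0.12) and FGB under gap-GR14 at 45 nM (−0.088) and 40 nM (−0.036), and turned the direction of the ribosomal list under gap-GR14 at 45 nM (adjusted p = 0.992) and of the oxidative phosphorylation list at 40 nM (0.996). It left 2 lists past the threshold for gap-GR14 at 45 nM, 2 at 40 nM and 2 for gap-GR14 against gap-GR18-2 at 40 nM, gave 0 genes for the interaction in limma, 610 genes that rose under both gap-GR14 and gap-GR18-2 at 45 nM, and held-out shifts of −0.64 and −0.57 for genes higher at 40 and 45 nM. Centring on medians reversed A2M under gap-GR14 at 40 nM (0.037) and gave 0 genes for the interaction and 1 for each dose step. The cause was not tested.

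The mean of the probe sets of a gene, which by construction adds probe sets that differ, reversed A2M in gap-GR14 against gap-GR18-2 at 45 nM (0.22) and against Control under gap-GR14 at 45 nM (0.17), gap-GR18-2 at 45 nM (−0.057) and gap-GR18-3 (0.0030). It reversed FGA in gap-GR14 against gap-GR18-2 at 40 nM (−0.0042) and 45 nM (−0.064), NDUFS1 there (0.38 and 0.29) and under gap-GR18-3 (−0.062), PECAM1 under gap-GR14 at 45 nM (0.87), PSPC1 under gap-GR18-2 at 45 nM (0.047) and gap-GR18-3 (0.42), and RGS5 under gap-GR18-2 at 45 nM (−0.19). It gave 51 genes for the gap-GR14 dose step and 0 for the gap-GR18-2 dose step and the interaction.

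Without the filter, where a gene can be represented by another probe set, CXCL2 under gap-GR18-1 (0.61), CYP3A4 (−0.17) and DERL3 (−0.050) in gap-GR14 against gap-GR18-2 at 45 nM, and NR4A1 under gap-GR18-2 at 45 nM (−0.062) reversed. Lists past the threshold numbered 12 for gap-GR14 at 40 nM, 11 at 45 nM, 8 for gap-GR18-2 at 45 nM and 3 for gap-GR18-3, the interaction gave 2 genes, and the held-out shifts of lower genes were 0.90 and 0.87. The stricter filter, which tests fewer genes, gave at least 2-fold 2069 and 1888 genes for gap-GR14 at 45 and 40 nM, 174 for gap-GR18-1, 1241 and 1110 for gap-GR18-2, 287 for gap-GR18-3, and 1552 and 1432 for gap-GR14 against gap-GR18-2 at 45 and 40 nM. It gave 4 genes for the interaction and 4 for the gap-GR18-2 dose step.

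With a correlation estimated for each list, 0 lists passed camera in each of the 8 comparisons. Fitting only the groups compared, with fewer arrays, gave 0 genes in limma for both dose steps and the interaction. Genes called by adjusted p alone, a wider set by construction, shared between gap-GR14 at 45 nM and another condition numbered 4281 rises and 4344 falls with 40 nM, 2040 and 1752 with gap-GR18-1, 2987 and 2827 with gap-GR18-2 at 45 nM, and 2319 and 1672 with gap-GR18-3. The held-out shifts of genes chosen that way were 0.57 and −0.30 for genes chosen at 40 nM and 0.535 and −0.29 at 45 nM. The span ratios of genes so called were over 1.5 times smaller, at 2.78 in place of 4.38 for gap-GR14 at 45 nM.

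The replicate numbers showed no clear pairing: residuals of arrays with the same number had a median r of 0.008 and at most 0.074, against up to 0.161 for other numbers. Yet 13 of 28 arrays were closest to their own number, more than the 1 in 4 that chance gives, so a weak pairing is not excluded. With the number as a replicate block, gap-GR14 at 45 nM gave 4519 rises and 4647 falls, no count of genes moved by over 1.5 times, and 2 named genes lost their call. Signal over background limits the genes under the filter, for which no change is reported.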
